A study of Homo sapiens with 10 samples.

How the data were processed

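Bulk RNA sequencing was carried out on ESI017, a human embryonic stem cell line, kept in the pluripotent state in the defined medium mTeSR1. Per the labels' protocols, cells were plated in 12-well plates 24 h before treatment. Cells then received no addition, recombinant WNT3A at 300 ng/ml for 6 h or 18 h, or the GSK3 inhibitor CHIR99021 at 8 µM for 6 h or 18 h. Messenger RNA was selected on poly-T beads and primed with random hexamers for paired-end libraries, per the labels' protocols. The 10 libraries make 5 groups of 2. The series' design text describes 2 biological repeats. The CHIR99021 18 h treatment was added in repeat 2, so both of its libraries belong to that repeat, and their replicate numbers are names given here. Every other group has 1 library from each repeat.

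The values the authors deposited are estimated counts per gene, 1 column per library. Salmon 1.8.0 and the human genome build GRCh38 are named in the submitters' processing notes. The step from transcripts to genes, the transcript set and any filter are not given in the sources used here. The kit's strand setting is likewise not given in the sources used here, so overlapping and antisense genes were not separated further. Estimated counts were rounded to whole numbers before any test. Library totals lay between 1.66e+07 and 2.67e+07, which places 3 counts at 0.112 to 0.180 CPM, counts scaled to a library total of 1e+06. Between 49.1% and 54.2% of values above 0 were whole numbers in repeat 1, and between 27.6% and 35.4% in repeat 2. All columns were matched to a sample by name.

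The table had 37951 genes by Ensembl identifier, of which 14620 were at 0 in all libraries. Of these identifiers, 35003 are on the primary assembly in GENCODE release 29, which supplied coordinates, and 2948 are not. Identifiers off the primary assembly include copies of genes on alternate haplotypes, among which reads of one gene can be divided. In total 3045 identifiers shared a symbol with another, and 1049 of those were among the genes tested. Values of such genes are given per identifier and are uncertain, and for POU5F1, ATF6B and TIMM22 the sum over the identifiers is given too.

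Differential expression was tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test with robust estimation. Trimmed-mean scaling (TMM) was used, with genes kept by a minimum count of 10 and a minimum total of 15, which left 15770 genes. All 10 libraries entered 1 fit, so that the groups shared an estimate of the spread. Genes with a Benjamini-Hochberg adjusted p (FDR) under 0.05 are reported as changed. Comparisons that involve CHIR99021 at 18 h had the biological repeat as a block, since that group has no library of repeat 1. The others had none, and each was refitted the other way. Levels are CPM with the SD of 2 libraries. P-values, and the 95% intervals of differences between treatments, measure the spread between libraries, while counting intervals and floors cover counting error only. For a group with 0 counts the fold is a bound from a floor of 3 counts per library. For a group with 1 to 3 counts it is a ratio with an exact 95% counting interval.

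The repeats pair the libraries by the series' design text. In a check of this, deviations from the group means correlated between same-numbered libraries with Pearson coefficients of 0.207 to 0.511 over 6 pairs of groups. In the blocked fit 267 genes were higher and 401 lower in repeat 2 than in repeat 1. No pair of replicates agreed within sampling noise. The chi-square of their counts per degree of freedom was 14.2 to 108, so each library was counted once.

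A total of 26 gene lists, of which 18 hold pathway genes and 8 hold markers of other cell types or of RNA quality, were tested with camera in limma 3.58.1. The correlation between genes was preset at 0.01 on log2 CPM with a prior count of 2, and p-values were adjusted over the 26 lists of a comparison. Each test was repeated with an estimated correlation and with fry, which asks only whether a list moves one way on balance. Of 234 list tests, 45 passed with the preset correlation, 17 with fry, and 0 with an estimated correlation in limma. The p-value with an estimated correlation stands beside each list that passed. Members are counted over all genes tested and adjusted over the list alone. A member stands for 1 identifier, that on the primary assembly where there is one, which can hold few of the gene's reads. In the streak list WNT3 was so at 0 CPM in mTeSR1 and after 6 h of WNT3A. Its 3 identifiers summed to 0.976 and 5.43 CPM by library totals. POU5F1 in the pluripotency list is a like case.

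Correlations of log2 changes were compared with 20 simulated sets of unchanged groups. For genes called for WNT3A, 20 sets were drawn in which CHIR99021 had no effect. All libraries were redrawn, mTeSR1 included, and both treatments shared the simulated mTeSR1 libraries. The correlations are taken across genes, which are not independent replicates. For comparisons with mTeSR1 the genes named are the 8 largest increases and the 8 largest decreases. They had to pass the test, reach a mean of 1 CPM in either group and move the same way in both repeats. For CHIR99021 at 18 h both libraries had to move the same way against mTeSR1 of repeat 2. Clone-based names were skipped. Up to 4 members per list with the lowest p-values were added, and elsewhere the numbers are 6 and 3. A panel of AXIN2, LEF1, SP5, NKD1, TBXT, MIXL1, EOMES, NODAL, POU5F1, NANOG, SOX2, CDX2, ID1, SOX17 and GATA3 was always examined. Genes outside this rule were chosen after their values were seen and are marked so. Groups, designs, lists, this rule and most alternatives were fixed before the data were examined.

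The procedure was tested on simulated data drawn from the library means of all 15770 genes. The 200 genes changed in each simulation were picked above a minimum average level. The shares below thus do not cover genes with low counts. For WNT3A at 6 h and at 18 h, 26% and 18% of genes changed 2-fold were called, and 64% and 80% of those changed 4-fold. For CHIR99021 at 6 h the shares were 23% and 76%, and at 18 h 40% and 85%. Between 2 and 7 unchanged genes were called in each simulation. Alternatives were the block, DESeq2 1.42.0, limma-voom, other scalings and filters, fits on fewer libraries, and leaving out each library. Summed identifiers, a correction for transcript length and GC content, a finer block and a fit without the CHIR99021 18 h libraries were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No genome sequence was used here.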

Results

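Gene expression was measured by RNA sequencing in ESI017 human pluripotent stem cells in mTeSR1 medium alone and after activation of the canonical WNT pathway. The pathway was activated with its ligand WNT3A, or with CHIR99021, a small molecule that inhibits GSK3, the kinase that marks β-catenin for degradation. Groups were untreated cells (mTeSR1), WNT3A at 300 ng/ml for 6 h and 18 h, and CHIR99021 at 8 µM for 6 h and 18 h, with 2 libraries each. Library totals in estimated counts were 1.89e+07 and 1.81e+07 in mTeSR1, 2.16e+07 and 2.67e+07 in WNT3A 6 h, 2.09e+07 and 1.73e+07 in WNT3A 18 h, 1.83e+07 and 1.82e+07 in CHIR99021 6 h, and 1.66e+07 and 1.73e+07 in CHIR99021 18 h. The design asks how these cells respond to the ligand over time, and whether a direct block of GSK3 gives the same response. The labels give no time for mTeSR1 and list no solvent control for CHIR99021. Changes against mTeSR1 and from 6 h to 18 h can thus include time in culture or, with CHIR99021, its solvent. Agreement between the treatments can include shared time in culture too. Principal components 1 and 2 of log2 CPM held 26% and 22.3% of the variance. Mitochondrially encoded genes took 3.94% and 6.73% of counts in mTeSR1 and 2.70% to 5.37% in the treated libraries.

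After 6 h of WNT3A, the largest increase in a gene with 1 identifier was in SP5, a transcription factor gene that WNT signalling induces directly. SP5 (ENSG00000204335, GRCh38 chromosome 2, 170715351 to 170718078) rose from 0.183 ± 0.259 CPM in mTeSR1 to 243 ± 96.1 CPM (SD, n = 2), a log2 change of 10.27 (SE 0.88, FDR 0.0041). With 0 counts in mTeSR1 replicate 2 this fold is uncertain, at 9.34 to 15.19 over 17 alternatives, and the call was lost in 4. AXIN2, a negative feedback regulator of the pathway (ENSG00000168646, chromosome 17, 65528563 to 65561647), rose from 35.6 ± 5.32 to 217 ± 46.6 CPM (log2 change 2.61, SE 0.34, FDR 0.020). The forkhead factor gene FOXB1 (ENSG00000171956, chromosome 15, 60004222 to 60061730) had the lowest FDR and rose from 1.86 ± 0.262 to 82.6 ± 14.7 CPM (log2 change 5.47, SE 0.27, FDR 0.00036). FOXD3, a forkhead repressor gene of pluripotent and neural crest cells (ENSG00000187140, chromosome 1, 63323041 to 63325126), fell from 49.8 ± 5.92 to 3.90 ± 1.02 CPM (log2 change -3.68, FDR 0.014). In all, 59 genes rose and 6 fell among 15770 tested with edgeR.

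The other named increases at 6 h of WNT3A included SEMA3C, a secreted guidance cue (log2 change 7.44, FDR 0.0094), GBX2, a homeobox factor of the midbrain-hindbrain boundary (5.84, FDR 0.037), the WNT receptor gene FZD10 (5.13, FDR 0.014), HERC3 (4.92, FDR 0.0087) and the growth factor gene FGF18 (4.85, FDR 0.014). Other decreases among the named genes were smaller, with FOXJ1, a regulator of motile cilia, at -2.36 (FDR 0.044), the cytokine gene TNFSF11 at -2.17 (FDR 0.043) and HS3ST5, a heparan sulfate sulfotransferase, at -1.62 (FDR 0.049). TIMM22 was called at 12.46, but 2 identifiers share this symbol and their summed level did not change (log2 change -0.00070, FDR 1).

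Of the 17 tested members of the list of WNT feedback and direct target genes, 6 rose after 6 h of WNT3A (AXIN2, TCF7, NKD1, SP5, TNFRSF19 and CCND1), and 12 rose adjusted over the list alone. Their median log2 change was 2.44 (camera adjusted p = 1.0e-22, and adjusted p = 0.10 with an estimated correlation). CCND1, which encodes cyclin D1, rose from 184 ± 37.3 to 792 ± 113 CPM (FDR 0.0041), and the WNT effector TCF7 from 13.5 ± 1.10 to 54.4 ± 1.17 CPM (FDR 0.024). NKD1, a feedback inhibitor, rose from 14.1 ± 3.24 to 258 ± 2.42 CPM (log2 change 4.20, FDR 0.044). With the repeat as a block the FDR was 0.095 for NKD1 and 0.083 for GBX2, and each call was lost in 11 of 17 alternatives. LEF1 was at 0.580 ± 0.659 and 21.9 ± 12.1 CPM and did not pass (log2 change 5.20, FDR 0.36).

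Among 14 tested genes of the primitive streak and mesendoderm, SP5 alone passed over all genes and 5 rose adjusted over the list alone, with a median of 2.40 (camera adjusted p = 1.1e-07, and adjusted p = 0.19 with an estimated correlation). TBXT, the brachyury gene (ENSG00000164458, chromosome 6, 166157656 to 166168700), had 0 counts in mTeSR1 and 11.2 ± 2.78 CPM after 6 h, at least 68.5-fold higher, without passing the test. Of 11 tested caudal and axial patterning genes, NKX1-2 rose (42.3 ± 2.35 to 538 ± 146 CPM, FDR 0.011) and 7 rose adjusted over the list alone. This list's median of 4.19, or 2.11 with genes near 0 counts at their bound, gave a camera adjusted p = 1.0e-09, and an adjusted p = 0.19 with an estimated correlation. Of 6 definitive endoderm genes, 3 rose adjusted over the list alone (median 2.21, camera adjusted p = 2.8e-04, and adjusted p = 0.26 with an estimated correlation). Sterol biosynthesis had a median of 0.15 over 16 genes (camera adjusted p = 0.0057, and adjusted p = 0.56 with an estimated correlation), with no member past the test by edgeR.

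Among 21 pluripotency genes FOXD3 was down after 6 h of WNT3A, and the list did not pass (median -0.16, camera adjusted p = 0.56). Outside these lists, the activin antagonist FST rose from 9.97 ± 3.58 to 262 ± 39.6 CPM (FDR 0.0073), the Notch ligand JAG1 by 1.17 log2 (FDR 0.043) and the YAP-associated AMOTL2 by 1.22 log2 (FDR 0.042). With the repeat as a block the 6 h count was 139 genes (117 up, 22 down), of which 63 were shared, and DESeq2 called 259. With the block, nascent mesoderm (camera adjusted p = 0.015) and the integrated stress response (camera adjusted p = 0.034) also passed as lower, against 0.056 and 0.059 without it, and had adjusted p = 0.20 and 0.52 with the block and an estimated correlation. The count was 5 without mTeSR1 replicate 1, 23 without mTeSR1 replicate 2 and 34 without WNT3A 6 h replicate 2. In mTeSR1 replicate 2 and WNT3A 6 h replicate 2 a gene's deviation from its mean rose with the length of its longest annotated transcript. Spearman correlations across genes were 0.414 and 0.511, against -0.339 to 0.0127 in the other 8 libraries.

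**Figure D1:**
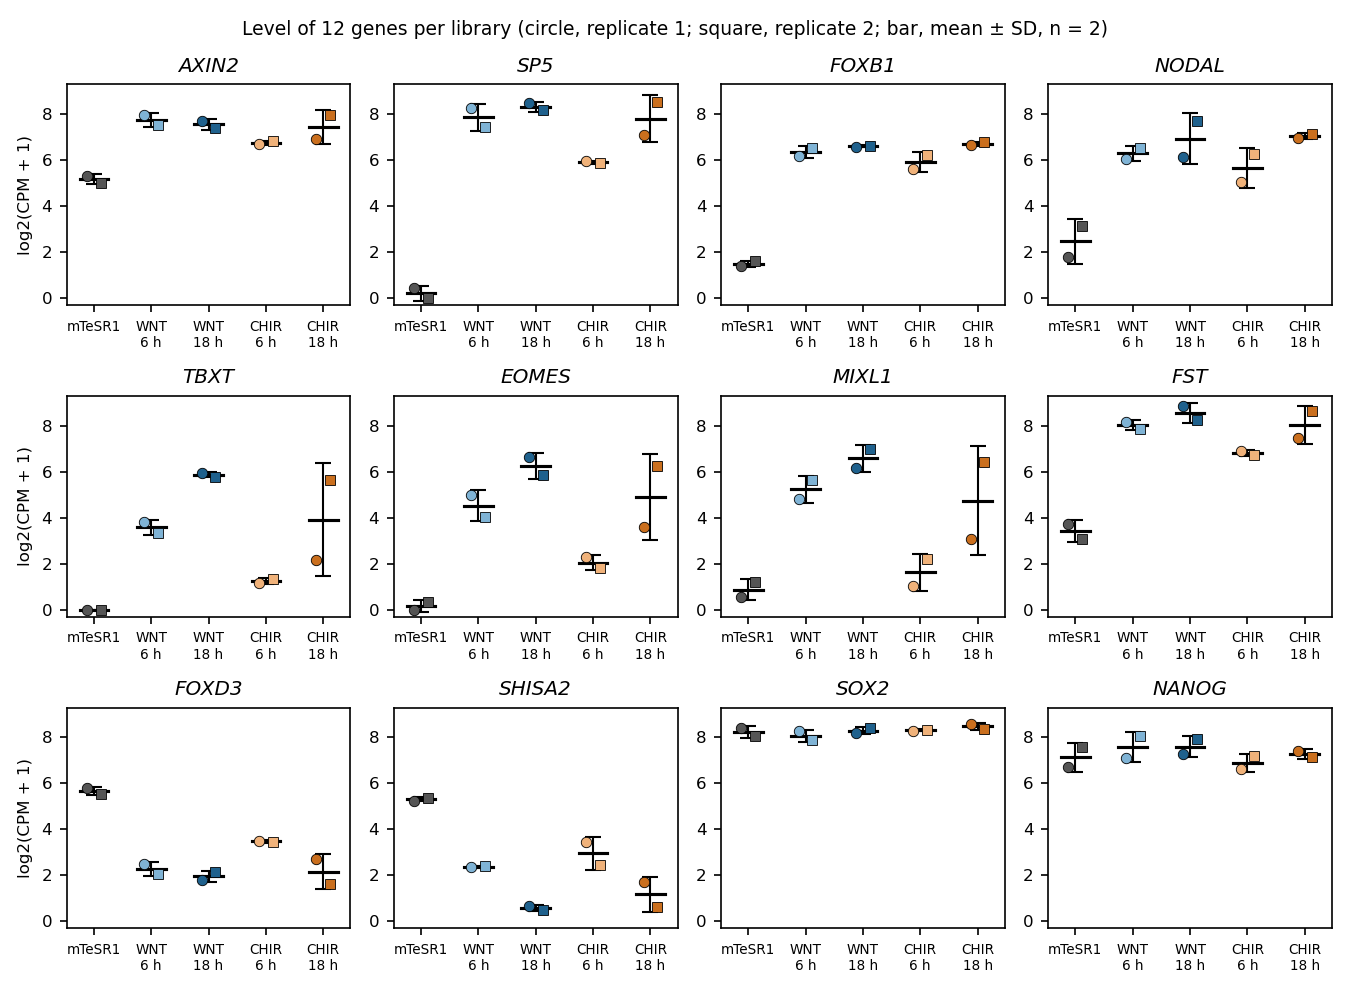
Levels of 12 genes as log2(CPM + 1) on the vertical axis in the 5 groups, with circles for replicate 1, squares for replicate 2, and bars for the mean ± SD (n = 2) of these log2 values. SP5 and TBXT lie near 0 in mTeSR1, FOXD3 and SHISA2 are highest in mTeSR1, and the CHIR99021 18 h libraries lie apart for TBXT (3.52 and 49.2 CPM), EOMES (11.2 and 74.8 CPM) and MIXL1 (7.40 and 84.3 CPM).

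**Figure D2:**
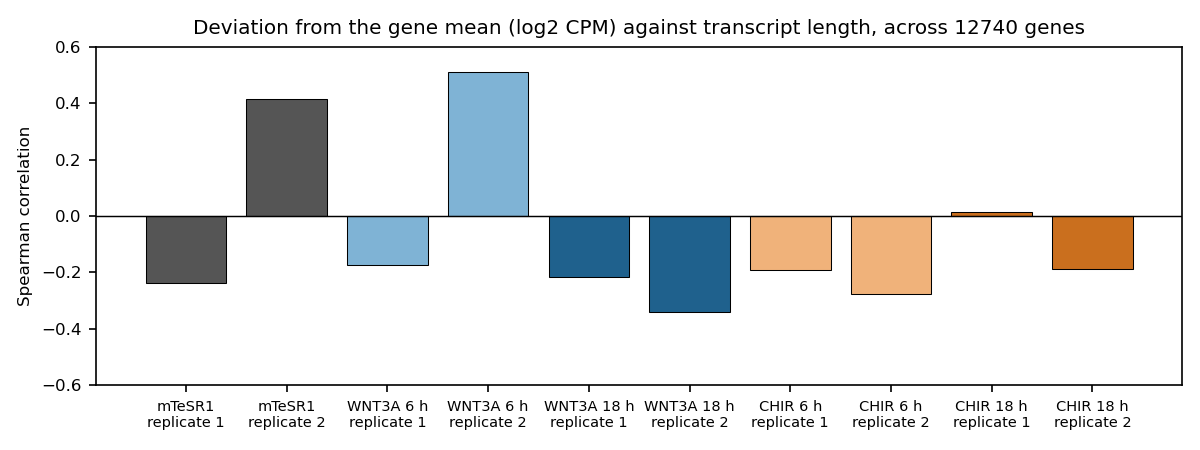
Spearman correlation (vertical axis) across 12740 genes between a gene's deviation from its mean and its transcript length, for each of the 10 libraries. mTeSR1 replicate 2 (0.414) and WNT3A 6 h replicate 2 (0.511) stand above the others, which reach 0.0127.

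After 18 h of WNT3A, genes of the primitive streak were among the largest increases. TBXT reached 57.6 ± 4.30 CPM (n = 2), at least 352-fold above its floor in mTeSR1 (FDR 0.049, with the call lost in 10 of 17 alternatives). EOMES, a T-box factor of mesoderm and endoderm (ENSG00000163508, chromosome 3, 27715949 to 27722711), rose from 0.142 ± 0.201 to 78.1 ± 29.7 CPM (log2 change 9.09, SE 1.35, FDR 0.022, at 8.05 to 13.57 over 17 alternatives and lost in 8). NODAL, the ligand that maintains the streak (ENSG00000156574, chromosome 10, 70432315 to 70447951), rose from 5.20 ± 3.88 to 140 ± 98.5 CPM (log2 change 4.76, SE 0.77, FDR 0.029), and SP5 reached 321 ± 47.8 CPM (FDR 0.0053). SHISA2, which encodes an inhibitor of WNT and FGF receptor maturation, fell from 38.6 ± 2.52 to 0.507 ± 0.148 CPM (log2 change -6.22, SE 0.67, FDR 0.0070). In all, 128 genes rose and 113 fell in edgeR's test.

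The ligand gene WNT8A and the HOX gene HOXB1 had 0 counts in mTeSR1 and rose at least 28.7-fold and 14.6-fold by 18 h of WNT3A (FDR 0.027 and 0.018), and the proline transporter gene SLC6A7 rose at least 10.6-fold (FDR 0.039). SEMA3C (log2 change 7.10, FDR 0.0070) and GAD1, which encodes an enzyme of GABA synthesis (6.71, FDR 0.020), rose as well. HESX1, an anterior homeobox repressor, fell by 4.75 on the log2 scale (FDR 0.0076), and SORBS2, an actin-associated adaptor, fell by 4.19 (FDR 0.015). The diacylglycerol kinase gene DGKK (-4.13, FDR 0.022), FOXD3 (-4.09, FDR 0.0070), TMEM26 (-4.06, FDR 0.046) and SEZ6 (-4.05, SE 0.29, FDR 0.0032) fell too. One ATF6B identifier also passed, at -10.37, while the sum over its 4 identifiers changed by 0.14 log2 (FDR 0.795).

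Of 14 tested streak and mesendoderm genes, 4 rose at 18 h of WNT3A (TBXT, EOMES, NODAL and SP5) and 9 rose adjusted over the list alone. Their median was 4.41, or 3.66 with genes near 0 counts at their bound (camera adjusted p = 2.6e-09, and adjusted p = 0.21 with an estimated correlation). MIXL1 was at 0.888 ± 0.591 and 99.3 ± 39.4 CPM and did not pass (FDR 0.063). WNT feedback and target genes had 6 increases (AXIN2, TCF7, NKD1, SP5, RNF43 and CCND1), and adjusted over the list alone 12 rose and 1 fell (median 2.42, camera adjusted p = 1.4e-10, and adjusted p = 0.21 with an estimated correlation). AXIN2 was at 190 ± 30.2 CPM (FDR 0.015). Caudal and axial genes had 4 increases (NKX1-2, HOXB1, WNT5B and WNT8A) among 11, and 8 adjusted over the list alone (median 6.42, or 4.42 at the bounds, camera adjusted p = 2.6e-09, and adjusted p = 0.21 with an estimated correlation). CDX2, a caudal homeobox gene, had 3 counts in mTeSR1 and 37.9 ± 17.6 CPM at 18 h, a ratio of 480 (counting interval 164 to 2329), without passing (FDR 0.10).

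Definitive endoderm genes had a median of 1.24 at 18 h of WNT3A (camera adjusted p = 0.014, and adjusted p = 0.43 with an estimated correlation), with FOXA2 rising from 0.360 ± 0.213 to 5.48 ± 1.62 CPM (FDR 0.021) and 2 of 6 rising adjusted over the list alone. Among pluripotency genes OTX2 (-2.49, FDR 0.021), UTF1 (-2.62, FDR 0.036) and FOXD3 were down. Adjusted over the list alone 3 of 21 rose and 5 fell, and the list did not pass (camera adjusted p = 0.051). SOX2 was at 303 ± 54.4 and 314 ± 36.3 CPM (FDR 0.94), NANOG at 146 ± 61.5 and 197 ± 61.5 CPM (FDR 0.73), and POU5F1, summed over its 4 identifiers, at 1301 ± 533 and 1702 ± 139 CPM. Further increases were in FST (5.26, FDR 0.0054), the BMP ligand BMP4 (2.05, FDR 0.029), ID2, a target of BMP signalling (2.73, FDR 0.018), the cadherin gene CDH11 (1.8, FDR 0.021) and the hypoxia-responsive genes PDK1 (2.23, FDR 0.0092) and BNIP3 (1.35, FDR 0.022). COL1A1, which encodes a collagen chain, fell by 1.04 (FDR 0.021).

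S phase genes had a small positive median at 18 h of WNT3A (0.17 over 16 genes, camera adjusted p = 0.026, and adjusted p = 0.26 with an estimated correlation). The 13 mitochondrially encoded transcripts had a median of -0.72 (camera adjusted p = 2.4e-04, and adjusted p = 0.51 with an estimated correlation), their share of counts being 2.70% and 4.10% in these libraries against 3.94% and 6.73% in mTeSR1. With the repeat as a block 594 genes were called (257 up, 337 down), 239 of them shared, and DESeq2 called 793. TBXT and NKD1 then missed the threshold (FDR 0.11 and 0.075). The count fell to 27 without mTeSR1 replicate 1, 39 without mTeSR1 replicate 2, 21 without WNT3A 18 h replicate 1 and 33 without WNT3A 18 h replicate 2.

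Between 6 h and 18 h of WNT3A, 6 genes rose and 11 fell in edgeR's test. PCDH10, a protocadherin gene, rose from 0.963 ± 0.361 to 16.9 ± 2.10 CPM (log2 change 4.11, SE 0.45, FDR 0.031), and CYP1B1, which encodes a cytochrome P450, by 3.31 (FDR 0.041). SEZ6, a neuronal membrane protein gene, fell from 9.32 ± 1.10 to 0.704 ± 0.0630 CPM (log2 change -3.72, FDR 0.010). CPLX2, which encodes a complexin of synaptic vesicle release, fell by 2.86 on the log2 scale, NEDD9, a scaffold protein gene, by 1.89, and the TCF co-repressor gene TLE3 by 1.8 (FDR 0.031). Streak and mesendoderm genes had a median of 1.58, or 1.44 at the bounds (camera adjusted p = 0.030, and adjusted p = 0.71 with an estimated correlation). Mitochondrially encoded transcripts had a median of -0.72, with 3 lower adjusted over the list alone (camera adjusted p = 9.2e-04, and adjusted p = 0.71 with an estimated correlation). With the repeat as a block 168 genes were called (54 up, 114 down), all 17 included, and DESeq2 called 386. The count was 52 without WNT3A 6 h replicate 1, 6 without WNT3A 6 h replicate 2, and 0 without either WNT3A 18 h library by edgeR.

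After 6 h of CHIR99021, FOXB1 was the only gene past the threshold, rising from 1.86 ± 0.262 to 61.4 ± 18.1 CPM (n = 2, log2 change 5.04, SE 0.27, FDR 0.00064). Panel genes with a positive change that did not pass included SP5 at 59.2 ± 2.56 CPM (log2 change 8.24, FDR 0.064), AXIN2 at 108 ± 5.90 CPM (1.60, FDR 0.42), NKD1 at 45.0 ± 4.55 CPM (1.68, FDR 0.97) and NODAL at 54.6 ± 31.8 CPM (3.40, FDR 0.53). TBXT was at 1.40 ± 0.226 CPM, at least 8.58-fold above its floor in mTeSR1 (FDR 0.97). With the repeat as a block 20 genes rose, among them SP5 (FDR 0.043), NODAL (3.43, FDR 0.016), SEMA3C (5.63, FDR 0.025), HERC3 (3.59, FDR 0.021), FST (3.52, FDR 0.033) and the homeobox gene PROX1 (3.18, FDR 0.043). All 20 were also called for WNT3A at 6 h in that fit. In edgeR 727 genes had an unadjusted p under 0.05, and DESeq2 called 70 genes. Without mTeSR1 replicate 1 the count was 2, and without mTeSR1 replicate 2 it was 3.

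By list, WNT feedback and target genes had a median of 0.95 after 6 h of CHIR99021, with 5 of 17 higher adjusted over the list alone (camera adjusted p = 2.9e-08, and adjusted p = 0.37 with an estimated correlation). Streak and mesendoderm genes had a median of 1.60 and 2 of 14 higher adjusted over the list alone (camera adjusted p = 1.0e-04, and adjusted p = 0.37 with an estimated correlation). Caudal and axial genes had a median of 2.49, or 1.21 at the bounds, and 2 of 11 higher adjusted over the list alone (camera adjusted p = 1.4e-06, and adjusted p = 0.37 with an estimated correlation). Mitochondrially encoded transcripts had a median of -0.43 (camera adjusted p = 0.0081, and adjusted p = 0.65 with an estimated correlation), at 3.71% and 5.02% of counts.

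**Figure D3:**
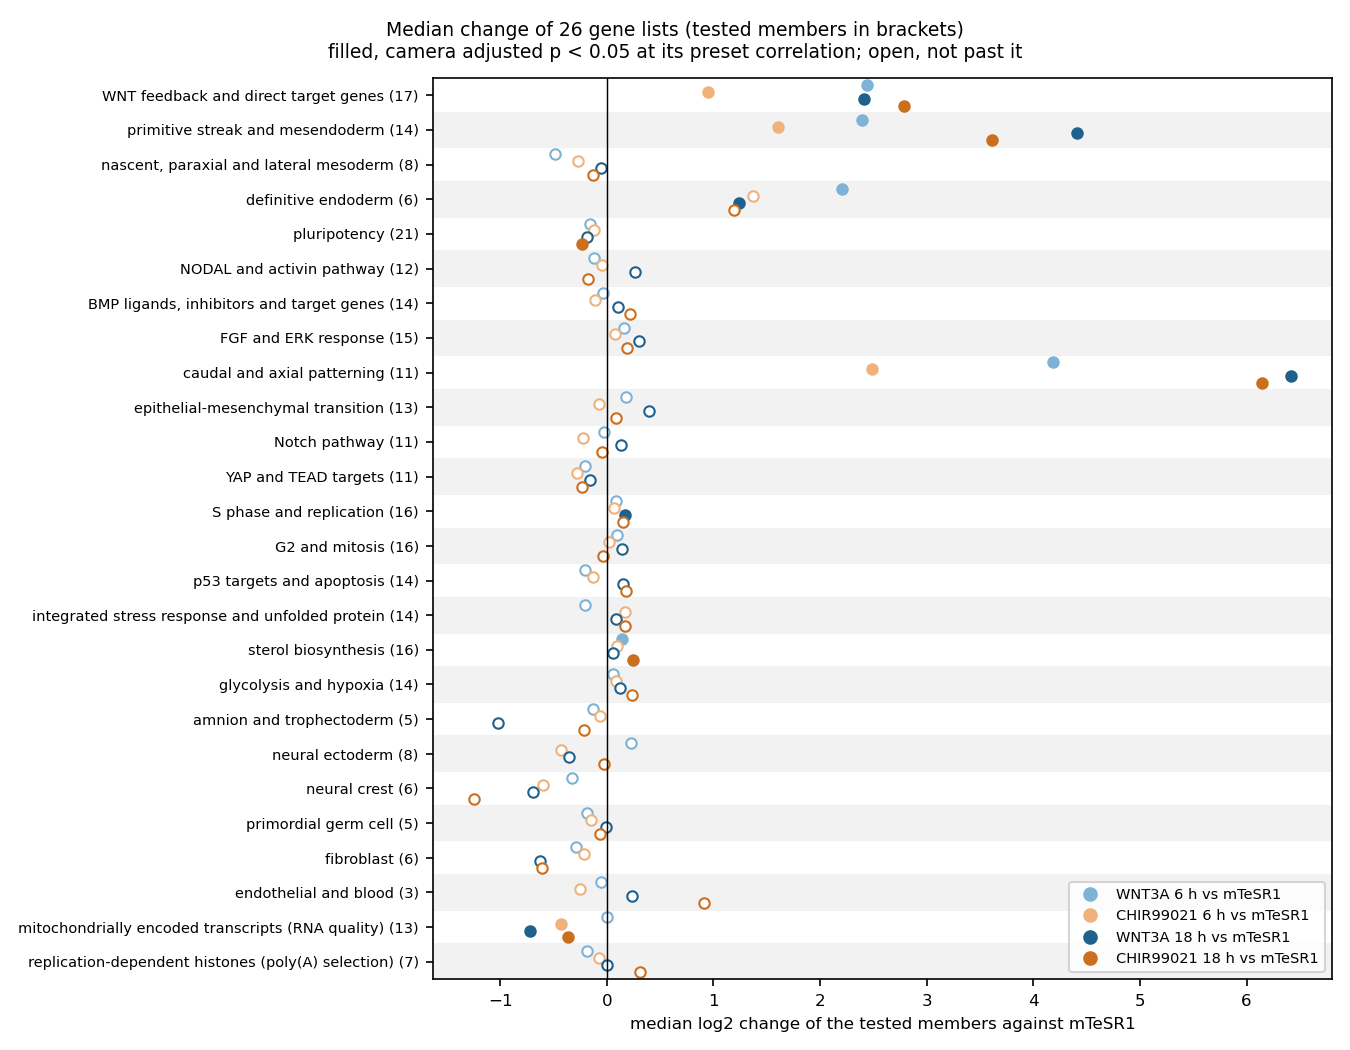
Median log2 change against mTeSR1 (horizontal axis) of the tested members of each of 26 gene lists, with a point for each of 4 comparisons, filled where the camera adjusted p is under 0.05 with the preset correlation. WNT target, streak and caudal lists lie to the right of 0 in all 4 comparisons, with medians from 0.95 to 6.42, and none of the 26 lists passed with an estimated correlation.

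After 18 h of CHIR99021, tested with the repeat as a block, 119 genes rose and 135 fell. Both libraries belong to repeat 2, and whether they come from separate wells is not given in the sources used here. If they do not, the SD and the FDR miss the spread between wells. Even if they do, the SD holds no spread between biological repeats. The FDR takes such spread from the other groups, so calls for this treatment rest on repeat 2 alone. SP5 rose from 0.183 ± 0.259 to 253 ± 166 CPM (n = 2, log2 change 10.59, SE 0.89, FDR 0.0078, at 9.69 to 15.26 over 16 alternatives and lost in 6), FOXB1 to 105 ± 6.59 CPM (5.65, SE 0.20, FDR 3.9e-05), and NODAL to 132 ± 11.4 CPM (4.24, SE 0.31, FDR 0.0033). ALK, a receptor tyrosine kinase gene, rose from 0.408 ± 0.0148 to 12.4 ± 4.10 CPM (5.23, SE 0.37, FDR 0.0021). SORBS2 fell from 27.9 ± 5.73 to 0.915 ± 0.816 CPM (-4.69, SE 0.55, FDR 0.012) and SHISA2 to 1.42 ± 1.20 CPM (-4.62, FDR 0.015).

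WNT8A rose at least 17.1-fold by 18 h of CHIR99021 (FDR 0.044), and GAD1 (6.99, FDR 0.041), SEMA3C (6.39, FDR 0.0052) and FST (5.11, FDR 0.0052) rose too. The homeobox gene MSX2 had 1 count in mTeSR1 and a ratio of 42.6 (counting interval 7.23 to 1726). Decreases included the glutamate receptor gene GRIK2, with 2 counts after treatment and a ratio of 29.1 (counting interval 7.72 to 245) of mTeSR1 over treated cells, and DGKK (-3.83, FDR 0.048), FOXD3 (-3.64, FDR 0.012) and HESX1 (-3.45, FDR 0.019). SYT4, a synaptotagmin gene, fell by 3.45 (FDR 0.014), and DNM3, a dynamin gene, by 3.32 (FDR 0.010). Without the block the FDR was 0.10 for MSX2, 0.13 for DNM3 and 0.0501 for GRIK2.

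WNT feedback and target genes had 5 increases after 18 h of CHIR99021 (AXIN2, TCF7, SP5, RNF43 and CCND1), 12 of 17 adjusted over the list alone, and a median of 2.79, or 2.51 at the bounds (camera adjusted p = 7.1e-08, and adjusted p = 0.49 with an estimated correlation). AXIN2 was at 185 ± 91.4 CPM (FDR 0.020). Streak and mesendoderm genes had 2 increases (NODAL and SP5), 7 adjusted over the list alone, and a median of 3.61, or 2.27 at the bounds (camera adjusted p = 2.1e-04, and adjusted p = 0.49 with an estimated correlation). TBXT (26.4 ± 32.3 CPM, FDR 0.17), MIXL1 (45.9 ± 54.4 CPM, FDR 0.16) and EOMES (43.0 ± 45.0 CPM, FDR 0.064, and 0.040 without the block) had an SD as large as the mean, the library named replicate 2 being the higher for each. Caudal and axial genes had 2 increases (NKX1-2 and WNT8A), 7 of 11 adjusted over the list alone, and a median of 6.14, or 3.41 at the bounds (camera adjusted p = 1.0e-05, and adjusted p = 0.49 with an estimated correlation).

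In pluripotency genes after 18 h of CHIR99021, KLF4 (1.90, FDR 0.045) rose and FOXD3 fell, and adjusted over the list alone 2 rose and 7 fell. This list's median was -0.23 (camera adjusted p = 0.021, adjusted p = 0.62 with an estimated correlation, and 0.10 without the block). SOX2 was at 355 ± 34.5 CPM (FDR 0.42) and NANOG at 154 ± 22.2 CPM (FDR 0.42). Sterol biosynthesis genes had a median of 0.25, with 2 higher adjusted over the list alone (camera adjusted p = 0.0030, and adjusted p = 0.57 with an estimated correlation). Mitochondrially encoded transcripts had a median of -0.37 (camera adjusted p = 0.047, adjusted p = 0.73 with an estimated correlation, and 0.75 without the block), at 5.12% and 5.14% of counts. FOXA2 (3.81, FDR 0.029), ID2 (2.65, FDR 0.031), PDK1 (1.66, FDR 0.010) and BNIP3 (1.38, FDR 0.027) rose, as did BMP4 (1.76, FDR 0.049, and 0.082 without the block). The ERK feedback gene DUSP6 (-1.78, FDR 0.025), the FGF target ETV5 (-1.14, FDR 0.043), the neurotrophin receptor gene NGFR (-2.14, FDR 0.032) and the peptide gene ADM (-0.95, FDR 0.032) fell. Without the block their FDRs were 0.076 for DUSP6, 0.082 for ETV5, 0.076 for NGFR and 0.20 for ADM.

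Without the block 152 genes were called for CHIR99021 at 18 h (89 up, 63 down), 145 of them shared, and DESeq2 with the block called 832. Endoderm genes as higher (camera adjusted p = 0.013, against 0.23 with the block) and neural crest genes as lower (0.012, against 0.074) passed only without the block, where their adjusted p was 0.45 and 0.23 with an estimated correlation. The count was 12 without mTeSR1 replicate 1, 6 without mTeSR1 replicate 2, 439 without CHIR99021 18 h replicate 1 and 67 without CHIR99021 18 h replicate 2.

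In the design used for each comparison, the remaining lists passed in none of the 4 comparisons with mTeSR1 in either direction with the preset correlation. The 3 of them that passed in the other design are given above. For WNT3A at 18 h their camera adjusted p was 0.070 for the NODAL and activin pathway (2 of 12 up), 0.12 for BMP ligands, inhibitors and targets (2 of 14 up), 0.58 for FGF and ERK response, 0.059 for epithelial-mesenchymal transition (1 of 13 up), 0.87 for the Notch pathway and 0.97 for YAP and TEAD targets (1 of 11 up). It was 0.11 for G2 and mitosis, 0.89 for p53 targets and apoptosis, 0.97 for the integrated stress response and 0.066 for glycolysis and hypoxia (3 of 14 up). For markers of other cell types it was 0.97 for nascent mesoderm (1 of 8 up), 0.60 for amnion and trophectoderm, 0.97 for neural ectoderm, 0.070 for neural crest (1 of 6 down, FOXD3), 0.89 for primordial germ cells, 0.24 for fibroblasts (1 of 6 down, COL1A1) and 0.89 for endothelium and blood. Replication-dependent histones, which poly(A) selection largely leaves behind, gave 0.79. For WNT3A at 18 h the median, the mean and the direction of the test differed in sign for nascent mesoderm, YAP targets, the integrated stress response, neural ectoderm and histones. Neural ectoderm markers differed between repeats, with mean log2 levels against mTeSR1 of 1.37 to 1.99 in the 4 libraries of repeat 1 and -1.97 to -0.653 in the 6 of repeat 2. SOX17 and GATA3 had too few counts to be tested, and ID1 was at 47.1 ± 0.957 CPM in mTeSR1 and 50.9 ± 31.4 CPM at 18 h of WNT3A (FDR 0.94).

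CHIR99021 and WNT3A were then compared directly at each time. At 6 h, 1 gene differed in edgeR's test, the clone-named AL513523.9, which was higher with CHIR99021 and is outside the rule for named genes. It was lost with the repeat as a block, where edgeR called 0 genes, against 1708 at an unadjusted p under 0.05 in that fit and 980 without the block, and DESeq2 called 41 (9 up, 32 down). Panel genes did not pass and differed, CHIR99021 minus WNT3A, by -1.01 log2 for AXIN2 (95% interval -1.74 to -0.28, FDR 0.71), -2.04 for SP5 (-3.25 to -0.82), -2.52 for NKD1 (-3.86 to -1.18) and -4.02 for MIXL1 (-6.74 to -1.30). For FOXB1 the difference was -0.43 (-0.92 to 0.06) and for NODAL -0.53 (-2.03 to 0.96, FDR 0.82). WNT feedback and target genes had a median of -1.19, with 9 of 17 lower adjusted over the list alone (camera adjusted p = 3.3e-10, and adjusted p = 0.51 with an estimated correlation). Streak genes had a median of -0.78 (camera adjusted p = 0.031, and adjusted p = 0.63 with an estimated correlation). The integrated stress response had a median of 0.33 (camera adjusted p = 0.0023, and adjusted p = 0.63 with an estimated correlation). Mitochondrially encoded transcripts had a median of -0.43 (camera adjusted p = 0.031, and adjusted p = 0.76 with an estimated correlation), with shares of 3.71% and 5.02% for CHIR99021 against 4.51% and 5.37% for WNT3A. Without WNT3A 6 h replicate 2 the count was 2, and without either CHIR99021 6 h library it was 0 by edgeR.

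At 18 h the only call between CHIR99021 and WNT3A was the ATF6B identifier ENSG00000234539 (log2 change 11.11, FDR 0.0094), whose 4 identifiers summed to a change of -0.015 (FDR 1). In edgeR 636 genes had an unadjusted p under 0.05, and DESeq2 called 18. Differences with 95% intervals were 0.09 (-0.66 to 0.85) for AXIN2, -0.11 (-1.34 to 1.12) for SP5, -0.07 (-0.43 to 0.29) for FOXB1, -0.50 (-1.11 to 0.12) for NODAL and -1.02 (-4.38 to 2.33) for TBXT. For NANOG the difference was -0.70 (-1.05 to -0.34), with an FDR of 0.93. Streak genes had a median of -0.88 (camera adjusted p = 4.0e-05, and adjusted p = 0.38 with an estimated correlation), and caudal genes -0.29 (camera adjusted p = 0.029, and adjusted p = 0.57 with an estimated correlation). Replicate 1 of CHIR99021 carried most of both, with list means over mTeSR1 of 2.18 in replicate 1 and 3.88 in replicate 2 for streak genes (WNT3A 4.06 and 4.24), and 1.88 and 3.58 for caudal genes (WNT3A 3.83 and 3.80). Sterol genes had a median of 0.23 (camera adjusted p = 1.4e-05) and mitochondrially encoded transcripts 0.38 (camera adjusted p = 3.5e-06), each with an adjusted p = 0.49 with an estimated correlation. The NODAL pathway (median -0.36, camera adjusted p = 8.1e-04, and adjusted p = 0.48 with an estimated correlation) was lower as well. So were YAP targets (median -0.17, adjusted p = 0.016) and G2 genes (median -0.19, adjusted p = 6.8e-04), both with an adjusted p = 0.38 with an estimated correlation. Without the block these became 0.36, 0.073 and 0.073. The count was 2 without WNT3A 18 h replicate 1, 3 without CHIR99021 18 h replicate 2 and 0 without CHIR99021 18 h replicate 1 by edgeR.

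**Figure D4:**
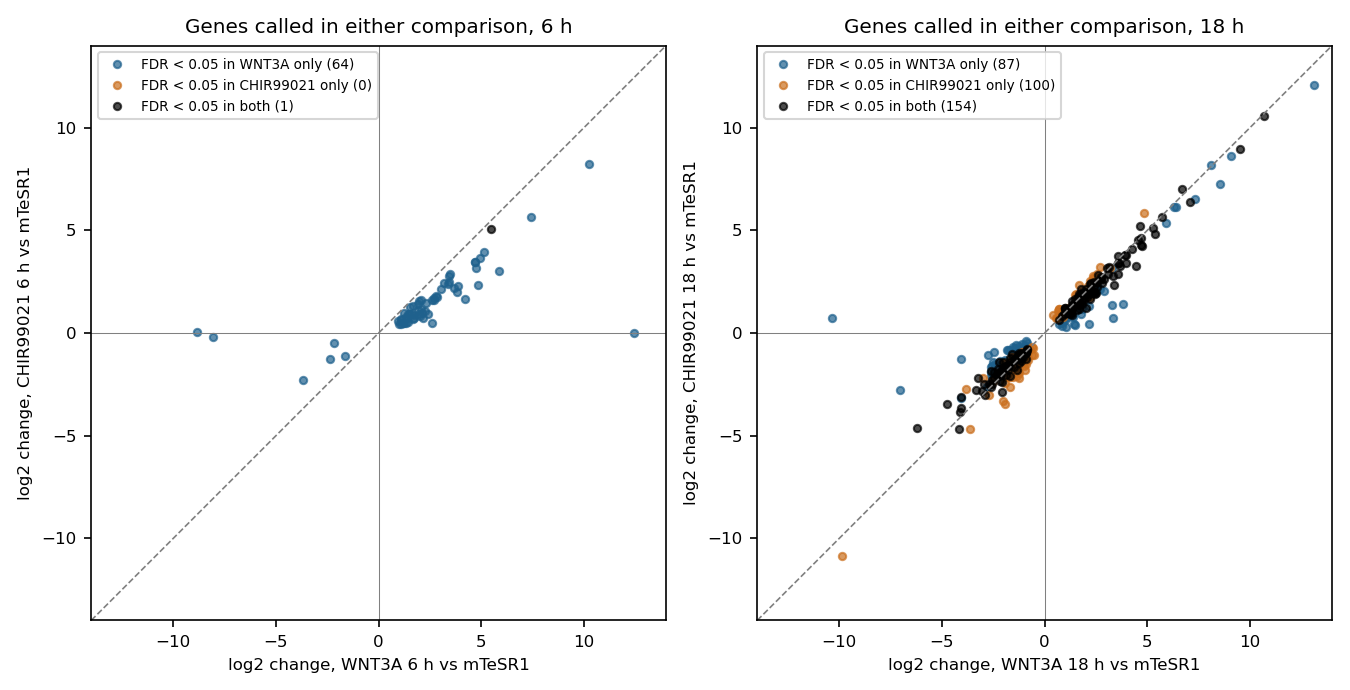
Log2 change against mTeSR1 with CHIR99021 (vertical axis) over that with WNT3A (horizontal axis) for genes called in either comparison, at 6 h (65 genes) and 18 h (341 genes), with colours for where a gene was called and a dashed line of equal change. The signs match for 63 of 65 genes at 6 h and 340 of 341 at 18 h, in part through the shared mTeSR1 libraries.

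Across all 15770 genes the log2 changes with CHIR99021 and WNT3A correlated with Pearson's r of 0.525 and Spearman's rho of 0.314 at 6 h. Unchanged groups simulated with shared, redrawn mTeSR1 libraries gave a mean r of 0.506 and a highest of 0.531. The 6 h sets held no pairing by repeat, so differences between repeats entered as independent spread. This reference may thus be too high. The covariance was 0.162 against 0.121 simulated, a difference of 0.0416. Between repeats, with no shared library, r was 0.127 and 0.238, and the mean covariance was 0.0878. For 1 treatment against itself across repeats, r was 0.342 for WNT3A and 0.147 for CHIR99021. At 18 h r was 0.784 and rho 0.769, against a simulated mean of 0.469 and highest of 0.495, and the covariance was 0.415 against 0.0857, a difference of 0.329. With no shared library r was 0.395 and the covariance 0.258, against an r of 0.435 for WNT3A with itself across repeats. CHIR99021 at 18 h has no such value, since both libraries belong to repeat 2. At 18 h 89 genes rose with both treatments, of 128 without the block for WNT3A and 119 with it for CHIR99021. In these designs 65 fell with both, of 113 and 135. With the block for both treatments, 112 rose with both, of 257 and 119, and 122 fell with both, of 337 and 135. Among genes called for WNT3A, the changes with CHIR99021 had the same sign for 96.9% at 6 h and 99.6% at 18 h, with slopes of 0.563 and 0.836. In 20 simulations with shared, redrawn controls and no effect of CHIR99021, the highest values were 71.4% and 66.7%, with slopes of 0.118 and 0.0703. These simulations called more genes (253 and 455 on average, against 65 and 241). They also leave out time in culture, which both treatments may share against mTeSR1.

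Between 6 h and 18 h of CHIR99021 edgeR called 0 genes, against 1043 at an unadjusted p under 0.05 and 126 in DESeq2 (63 up, 63 down). The test carries the repeat as a block, since both CHIR99021 18 h libraries belong to repeat 2. WNT feedback and target genes had a median of 1.02 (camera adjusted p = 2.6e-05), streak genes 2.23, or 1.53 at the bounds (camera adjusted p = 0.0030), caudal genes 3.27 (camera adjusted p = 0.0012) and sterol genes 0.17 (camera adjusted p = 0.0013). Pluripotency genes had a median of -0.25 (camera adjusted p = 0.0045, and 0.068 without the block), neural crest genes -0.65 (camera adjusted p = 0.027), and p53 targets 0.17 (camera adjusted p = 0.050, and 0.67 without the block). Each of these 7 lists had an adjusted p = 0.53 with an estimated correlation. Without the block 6 lists passed with the preset correlation, not all of them among these 7, and 0 with an estimated correlation in limma. Replicate 2 at 18 h carried most of the first 3 increases. List means over mTeSR1 were 1.41 and 1.39 at 6 h against 1.64 in replicate 1 and 2.91 in replicate 2 at 18 h for WNT genes. They were 1.59 and 1.94 against 2.18 and 3.88 for streak genes, and 1.57 and 1.47 against 1.88 and 3.58 for caudal genes. Adjusted over the list alone 4 WNT genes, 4 caudal genes, 2 streak genes and 2 p53 targets were higher, and 1 streak gene and 2 neural crest genes lower. The count was 68 without CHIR99021 18 h replicate 1 and 1 without either CHIR99021 6 h library.

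The change from 6 h to 18 h was also compared between treatments. By edgeR the ATF6B identifier ENSG00000234539 was the only gene whose change differed (log2 difference 11.41, FDR 0.021), with 573 genes at an unadjusted p under 0.05 and 12 in DESeq2. The summed ATF6B identifiers gave -0.24 (FDR 0.93). WNT feedback and target genes moved upward by a median of 1.29 more with CHIR99021 than with WNT3A (camera adjusted p = 9.9e-08, and adjusted p = 0.75 with an estimated correlation), and 1 member passed adjusted over the list alone. CHIR99021 18 h replicate 2 carried most of the rise, at a list mean of 2.91 against 1.64 in replicate 1. With WNT3A the list means were 3.13 and 2.53 at 6 h and 2.85 and 2.32 at 18 h. Leaving out 1 library at a time gave counts of 0 to 3 in edgeR.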

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

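The tests on summed identifiers in this part were chosen after the result was seen. In edgeR, 1 gene changed differently between 6 h and 18 h under CHIR99021 than under WNT3A. This was ATF6B, an endoplasmic reticulum stress transcription factor gene, at the identifier ENSG00000234539 (log2 difference 11.41, SE 0.76, FDR 0.021). That identifier had 0 counts in both WNT3A 18 h libraries and 4.35 to 13.0 CPM in the other 8. ATF6B has 4 identifiers, and their sum had means between 25.1 and 30.8 CPM in the 5 groups. TIMM22, a mitochondrial import gene with 2 identifiers, behaved alike, at 30.8 and 39.5 CPM for 1 identifier in the WNT3A 6 h libraries and 0 elsewhere, with mean sums of 39.6 to 44.6 CPM. CPM of these identifiers and sums are by library totals, without TMM. One explanation is that estimated counts were divided differently between the copies of a gene from group to group. Summed identifiers then should not change, and the largest summed change among these comparisons was -0.24 log2 (FDR 0.93), which fits. A change in ATF6B itself is thus not needed for this result.

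Of the 26 lists, 4 had a change between 6 h and 18 h that differed between treatments in limma's camera with its preset correlation. WNT feedback and target genes moved up more with CHIR99021 (median 1.29, adjusted p = 9.9e-08, and adjusted p = 0.75 with an estimated correlation). CHIR99021 18 h replicate 2 carried most of this, with a list mean over mTeSR1 of 2.91 against 1.64 in replicate 1 and 1.41 and 1.39 at 6 h. Sterol biosynthesis did so too (median 0.31, adjusted p = 2.7e-06, and adjusted p = 0.75 with an estimated correlation). The integrated stress response had a negative difference (median -0.26, adjusted p = 0.0029, and adjusted p = 0.77 with an estimated correlation). From 6 h to 18 h its median was -0.059 with CHIR99021 and 0.15 with WNT3A. Mitochondrially encoded transcripts had a positive difference (median 0.76, adjusted p = 4.4e-10, and adjusted p = 0.75 with an estimated correlation), as did 9 of 13 members adjusted over the list alone. From 6 h to 18 h their median was 0.043 with CHIR99021 and -0.72 with WNT3A, so the difference reflects the fall with WNT3A. None of these lists had a member past the test over all genes.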

How the results depend on the processing

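Counts of changed genes are set here against other ways of running each test. Summing the identifiers of a symbol, removing the transcript length and GC trend, splitting the block, and fitting without the CHIR99021 18 h libraries were chosen after the data were seen. For each count that moved, the cause was not tested. Alternatives for normalized values (another pseudocount, no filter on low values, quantile scaling) were not run, since the values are counts. Other scalings, a filter at 1 CPM in 4 libraries, and settings not named for a result left its count within 1.5 times.

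For WNT3A at 6 h (65 genes) the repeat as a block gave 139, no low-count filter 123, limma-voom 41 and DESeq2 259. A fit on the 4 libraries compared gave 0, with 592 genes at an unadjusted p under 0.05 in edgeR. The block with the length and GC trend removed gave 225, and the block with repeat 2 split by its length trend 469. For WNT3A at 18 h (241 genes) the block gave 594, no filter 395, DESeq2 793, the block with the trend removed 981 and the split block 659.

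For CHIR99021 at 6 h (1 gene) the block gave 20, no filter 10, DESeq2 70, only the groups compared 8, summed identifiers 3 and the fit without the CHIR99021 18 h libraries 13. Removing the length and GC trend gave 9, doing so with the block 34, and the split block 49. For CHIR99021 at 18 h (254 genes) the fit without the block gave 152, DESeq2 832, only the groups compared 868, repeat 2 alone 666, summed identifiers 421, the trend removed 638 and the split block 164. One of 4 POU5F1 identifiers, ENSG00000204531, reversed in the split block at 18 h of CHIR99021, with a log2 change of -0.98 against 0.19. It held 8.19 of 1678 CPM summed over the 4 in mTeSR1 replicate 1, and the summed change was 0.52 (FDR 0.41), which was not run with the split block.

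Between CHIR99021 and WNT3A at 6 h (1 gene) the block gave 0, with 1708 genes at an unadjusted p under 0.05 in edgeR. No filter gave 5, limma-voom 2, DESeq2 41, only the groups compared 8 and the fit without the CHIR99021 18 h libraries 4. The trend removed gave 2, doing so with the block 6, and the split block 11. At 18 h (1 gene) limma-voom gave 0 and summed identifiers 0 in edgeR, with 677 and 628 genes at an unadjusted p under 0.05. DESeq2 gave 18, only the groups compared 6, repeat 2 alone 4 and the split block 11.

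From 6 h to 18 h of WNT3A (17 genes) the block gave 168, no filter 163, limma-voom 7, DESeq2 386, only the groups compared 2 and the fit without the CHIR99021 18 h libraries 26. The trend removed gave 69, doing so with the block 473, and the split block 216. From 6 h to 18 h of CHIR99021 (0 genes) no filter gave 4, DESeq2 126, only the groups compared 1, repeat 2 alone 1, summed identifiers 1, the trend removed 7 and the split block 38. For the difference in change between treatments (1 gene) no filter gave 2, DESeq2 12, repeat 2 alone 416 and the split block 8. There limma-voom gave 0, only the groups compared 0 and summed identifiers 0 in edgeR, with 609, 562 and 574 genes at an unadjusted p under 0.05.

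With identifiers summed, the large changes of TIMM22 became -0.00070 for WNT3A at 6 h and 0.0089 from 6 h to 18 h of WNT3A. Those of ATF6B became 0.14 for WNT3A at 18 h, 0.19 from 6 h to 18 h of WNT3A, -0.015 between treatments at 18 h and -0.24 for the difference in change. The construction shows why, since the reads of 1 symbol are then counted together.

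With a library left out, the lone library of a group is assumed to vary like the other groups. Counts ranged from 5 to 56 for WNT3A at 6 h, 21 to 39 at 18 h, 1 to 3 for CHIR99021 at 6 h and 6 to 439 at 18 h. Between treatments they ranged from 0 to 2 at 6 h and 0 to 3 at 18 h in edgeR. From 6 h to 18 h they ranged from 0 to 52 for WNT3A, 0 to 68 for CHIR99021 and 0 to 3 for the difference in change in edgeR.

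The correlation of the responses at 6 h (0.525) ranged from 0.322 to 0.703 with a library left out, was 0.807 over called genes and 0.182 with no shared library. At 18 h (0.784) it ranged from 0.583 to 0.836, was 0.964 over called genes and 0.395 with no shared library. Of the 45 list tests past camera in limma, 0 passed with an estimated correlation, and fry passed 17 of the 234 list tests.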

Other observations

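Families were chosen here after the values were seen, as were the tests on libraries and the RE1 test on 5 family members, while the other RE1 test and that of base composition were written before they were run. Some genes of synapses fell at 18 h, a group that none of the fixed lists holds. Of 42 tested members of 6 gene families of synapses and secretory granules (synaptotagmins, synapsins with synaptophysin, neurexins with neuroligins, complexins, chromogranins and kainate receptors), 7 fell after 18 h of WNT3A (CPLX2, GRIK4, NLGN4X, SYN1, SYP, SYT11 and SYT2), and 16 with the block. After 18 h of CHIR99021, 8 fell, and 3 without the block. The chromogranin family had no member among the 7 and the 8, and 3 among the 16. Since the families were picked for such decreases, no p-value is given for the group. SYP, which encodes synaptophysin of synaptic vesicles, went from 21.6 ± 5.67 CPM to 3.62 ± 1.14 with WNT3A (-2.57, FDR 0.022) and 3.54 ± 1.33 with CHIR99021 (-2.28, FDR 0.0082). CPLX2, a complexin gene, fell by 3.07 and 2.84 (FDR 0.0087 and 0.014), and NPTX1, a neuronal pentraxin gene, fell by 2.59 and 2.62 (FDR 0.029 and 0.015). SYPL2, a synaptophysin-like gene of muscle, rose in both. Over the 42 genes the median was -0.12 after 6 h and -0.58 after 18 h of WNT3A, and -0.28 and -0.61 with CHIR99021.

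REST, the repressor of neuronal genes that binds RE1 sites, was at 62.8 ± 0.882 CPM in mTeSR1, 167 ± 22.6 after 6 h of WNT3A (FDR 0.019), 149 ± 27.8 after 18 h (FDR 0.017) and 128 ± 15.1 after 18 h of CHIR99021 (FDR 0.032). After 6 h of CHIR99021 it was at 91.2 ± 10.4 CPM (log2 change 0.54, FDR 0.97). The mean was highest at 6 h of WNT3A, with an SD that overlapped that at 18 h. After 6 h of CHIR99021 the 42 family genes already had a median of -0.28, while REST was not called. Whether REST rose before the decreases is thus not shown. Repression through RE1 sites could link these changes. If so, genes lower after 18 h of both treatments should carry the RE1 core more often. The core was searched in annotated transcripts, on either strand, with up to 2 mismatches, so a match need not be a true site. A match lay in 25 of 65 such genes (38.5%) against 16.4% of other tested genes. The odds ratio was 3.19 (interval 1.85 to 5.40, Fisher's exact p = 2.5e-05). Of the 5 family members lower with both (CPLX2, NLGN4X, SYN1, SYP and SYT11), CPLX2 alone carried a match (20%, Fisher's exact p = 0.59). For synaptic genes the explanation thus stays open. Matched by length and GC content, permutation draws held 16.9 genes with a match on average (p = 0.014). Base composition was tested with the reversed core, at an odds ratio of 2.56 (0.671 to 6.94, Fisher's exact p = 0.081), which leaves it open. Only transcript sequence was searched, so sites outside exons were not analysed here.

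Components of the WNT pathway itself changed in opposite directions. The receptor gene FZD10 was the only member of 10 tested FZD genes to rise in 3 comparisons, WNT3A at 6 h and 18 h and CHIR99021 at 18 h (log2 change 5.13, 4.69 and 4.63). FZD1 rose with CHIR99021 at 18 h (2.75, FDR 0.039, and 0.25 without the block). With WNT3A at 18 h FZD1 changed by 2.70 (FDR 0.13, and 0.021 with the block). FZD8 changed by -3.16 with WNT3A at 18 h (FDR 0.066, and 0.0035 with the block). SFRP1, which encodes a secreted WNT inhibitor, fell from 837 ± 203 to 87.0 ± 48.9 CPM at 18 h of WNT3A (-3.27, FDR 0.020) and 140 ± 42.3 CPM with CHIR99021 (-2.21, FDR 0.019, and 0.052 without the block). Of the TCF and LEF genes, TCF7 rose in the same 3 comparisons while TCF7L1, a repressor in pluripotent cells, fell from 296 ± 22.4 to 91.5 ± 19.5 CPM at 18 h of WNT3A (FDR 0.031). Of 6 TLE co-repressor genes, TLE3 rose at 6 h of WNT3A (79.1 ± 3.95 to 420 ± 54.7 CPM, FDR 0.0039) and not at 18 h (FDR 0.20). TLE2 fell at 18 h with both treatments (-1.78 and -1.82, FDR 0.021).

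The 2 CHIR99021 18 h libraries differ in late genes, with TBXT at 3.52 and 49.2 CPM, CDX2 at 0.955 and 41.4 CPM, and NODAL alike at 124 and 140 CPM. A mixture of the replicate 2 profile with untreated RNA would give genes that fall and late genes the same fraction of the replicate 2 change. The median fraction was 0.837 in 236 genes lower after 18 h of WNT3A and 0.351 in 38 late genes. Their difference was 0.486 (bootstrap interval over genes 0.359 to 0.567), and 0.350 (0.228 to 0.510) with mTeSR1 replicate 1 as the untreated profile. This goes against a mixture as the sole cause. It was at most 0.0294 between the WNT3A 18 h libraries, on which the genes were chosen, but -0.924 to 0.480 between 6 h replicates, with 12 to 18 late genes, so a mixture is not excluded. A mislabelled CHIR99021 6 h library was tested in 2 ways. On the WNT3A time axis of 168 genes replicate 1 lay 0.297 beyond the CHIR99021 6 h library of its repeat, with an interval from the spread between libraries of -0.0315 to 0.626, which alone leaves it open. The second test was added after that one. Genes lower after 18 h of WNT3A had a median 0.717 log2 further down in replicate 1 than in the CHIR99021 6 h libraries (difference -0.717). The 95% interval from the spread between 6 h libraries was -1.24 to -0.195. Genes higher after 18 h of WNT3A had a median 0.626 further up (0.478 to 0.774). Both go against a mislabelled 6 h library. That spread rests on 2 libraries per group, and the first test left the explanation open, so it is not excluded. A swap of replicate 2 with WNT3A at 18 h stays open. Over 41 genes that separate the treatments at 6 h in DESeq2, from 0 for WNT3A to 1 for CHIR99021, it lay at 0.742. The WNT3A 18 h libraries lay at 0.447 and 0.704, so these genes do not separate the treatments at 18 h. The ATF6B identifier ENSG00000234539 had 217 counts in replicate 2 and 0 in both WNT3A 18 h libraries, which goes against a swap but is 1 identifier picked after it was seen.

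mTeSR1 replicate 2 and WNT3A 6 h replicate 2 share a trend with transcript length. For mTeSR1 replicate 2 the partial correlation with GC content was 0.0406 against 0.409 for length. This goes against a steady rise or fall with GC content as the source there. In WNT3A 6 h replicate 2 the partial correlation with GC content was -0.243 against 0.458, which leaves a part for GC content open there. A GC bias of another form was not tested. The 76 ribosomal protein genes are too few to move a correlation over 12740 genes, so leaving them out was no test. The other 12664 genes kept correlations of 0.411 and 0.508, against at most 0.0159 in the other 8 libraries. The trend is thus not confined to ribosomal protein genes. Ribosomal protein genes were lower than genes of like length by a median of -0.342 and -0.645 log2, against -0.0166 to 0.265 elsewhere. Length was that of the longest annotated transcript, which need not be the one expressed. Whether length accounts for all of their change thus stays open. Loss of short transcripts stays open, since the correlation of 0.411 restates the trend.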
